A study of Mus musculus with 6 samples.

How the data were processed

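Total RNA of mouse embryonic lungs was measured on 6 Affymetrix Mouse430_2 arrays, 3 labelled wild type and 3 labelled GATA6 KO. The labels do not say whether each array holds the RNA of 1 embryo, whether arrays share a litter, or whether some are technical repeats, and each array was treated as an independent replicate. The deposited values are linear probe set intensities. The submitters' processing notes name GCRMA and MAS5 without a version, a role or an order, so which of them made the intensities is not stated. The values were checked: none is negative, the lowest per array lies between 2.04 and 2.07, the highest between 67170 and 69370, and the quantiles of the arrays lie close together. The arrays were therefore taken as already normalised to each other, which the notes do not state. The experiment files of the arrays were read for the chip type, the fluidics station and the order of scanning, and hold no expression values.

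Intensities were transformed to log2 after adding a pseudocount of 16, with no further scaling. Probe sets were named from the gene IDs of the array's annotation through a gene table of assembly GRCm38.p6, used for names and neighbours only. Of 45101 probe sets, 64 controls were left out, 932 named several genes, 9160 had no gene name here and 34945 named 1 gene, 34741 of them through a current gene ID. Each of the 18193 genes was represented by the probe set with the highest mean over all 6 arrays among those that name exactly 1 gene. Of 9010 genes with more than 1 probe set, the probe sets disagreed in the sign of the difference for 4342. No filter on dim genes was applied. A gene was called dim where both group means lay below 6.88 log2, the median of the genes' means.

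The difference between the arrays labelled KO and those labelled WT was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Every adjusted p for a gene comes from this limma fit. Errors on differences are the standard errors of that fit, and errors on group means are standard deviations over 3 arrays. The 40 gene lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, adjusted over the 40 lists. Camera with a correlation estimated from the residuals and fry were alternatives. Some genes stand in more than 1 list, such as Aqp5, Lpcat1, Etv5, Hhip and Id2. The lists, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined.

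The rule named Gata6 and the other GATA factors and cofactors. It then named bright genes past the threshold whose arrays do not overlap between the labels, up to 12 per direction, and where none pass the 5 with the smallest p per direction, said not to have passed. In each list it named up to 4 members past the threshold, and where none pass the first 2 measured members as values. Further names are given as chosen after their values were seen. Some members of mostly dim lists are given only as near the floor.

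The numbers 1 to 3 of the arrays were not taken as pairs. Residuals of arrays with the same number, after removing group means, correlated across genes at -0.613, 0.0971 and -0.311, and 0 of the 6 arrays lay closest to the array of its own number in the other group. The replicate block was run as an alternative all the same. Other alternatives were eBayes without the trend or robust, array quality weights, median centring, quantile normalisation, a filter on dim genes, other choices of probe set, pseudocounts of 1 and 64, leaving out each array in turn, fluidics station as a block, and a minimum of 1.5-fold. The covariate for RNA composition, which is each array's median of bright unnamed minus bright named probe sets, and the fit on the 4 arrays of station 2 were added after the data were seen.

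The steps were tested on simulated data with 18193 genes and 3 arrays per group. For the comparison of genes, 37 of 100 genes with a simulated change of 1 log2 (37%) and 76 of 100 with a change of 2 log2 (76%) were recovered, all with the right sign, and 4 unchanged genes were called. All changed genes were drawn from those whose mean in the arrays labelled WT lay above the median, and were changed in the same run. These rates thus do not cover dim genes or data in which few genes change. With no simulated change, 5.35% of genes had an unadjusted p under 0.05 and 0 were called in limma. For the comparison of lists, 1 of 40 simulated lists was shifted, and camera with the preset correlation, camera with an estimated correlation and fry all called it. The preset correlation also called 1 of the unshifted lists, the other two tests none. Each simulated gene varied independently of the others. Genes of a list can vary together in the real arrays, with an estimated correlation of 0.572 for cholesterol synthesis. The simulation thus does not show how the list tests compare on such lists. Splits of the 6 arrays into groups of 3 were counted once each, 10 in all.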

Results

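Whole lungs were taken from mouse embryos at E18.5, shortly before birth, and their total RNA was hybridised to Affymetrix Mouse430_2 expression arrays. The series asks which genes the zinc finger transcription factor GATA6 regulates in the lung. It compares 3 arrays labelled wild type (WT 1, WT 2 and WT 3) with 3 arrays labelled GATA6 KO (KO 1, KO 2 and KO 3). Each array holds a linear intensity for 45101 probe sets, 64 of them controls. The median intensity per array lay between 20.6 (WT 2) and 24.1 (KO 3), and the number of arrays limits the precision of every value below. All 6 arrays were hybridised on the same date. The arrays labelled WT 1 and WT 2 were washed on fluidics station 1, and the array labelled WT 3 and all 3 labelled KO on station 2. The arrays labelled WT were scanned before those labelled KO, so that scan order and group cannot be told apart.

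The largest difference between the lungs ran across the labels. On the first principal component, which held 45.1% of the variance over genes, the arrays labelled WT 1, KO 2 and KO 3 scored 23.1, 16.8 and 29.9, and those labelled WT 2, WT 3 and KO 1 scored -14.1, -23.0 and -32.8. The same 3 arrays, WT 1, KO 2 and KO 3, also carried more signal on bright probe sets that name no gene. Their median was -0.87, -1.19 and -0.66 log2 relative to that of bright named probe sets, against -1.98, -1.89 and -1.97 in the arrays labelled WT 2, WT 3 and KO 1. The second component, with 28.4% of the variance, put all 3 arrays labelled WT below 0 (-19.9, -26.5 and -4.23) and all 3 labelled KO above it (23.4, 4.37 and 22.9).

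**Figure D1:**
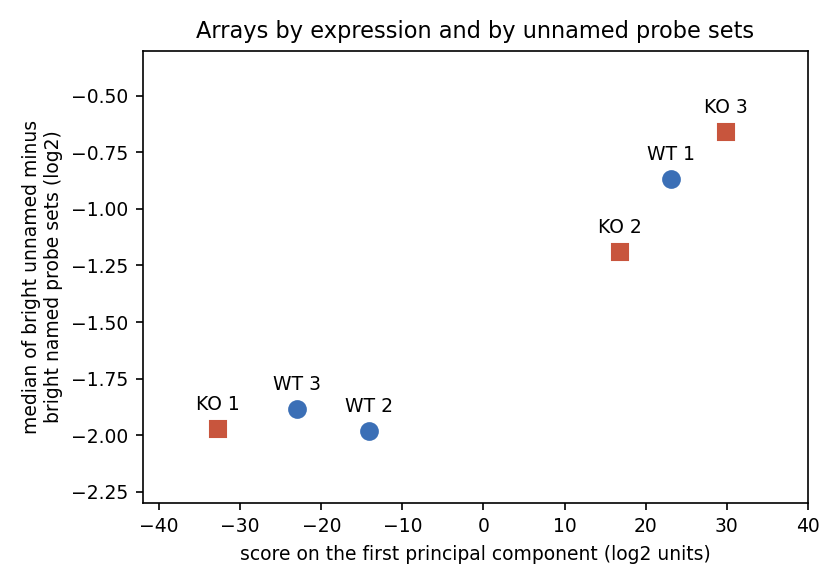
Each point is 1 array, in blue circles for the arrays labelled WT and red squares for those labelled KO, placed by the score on the first principal component (horizontal, log2 units) and the median log2 value of bright unnamed minus bright named probe sets (vertical). The arrays labelled WT 1, KO 2 and KO 3 lie at the upper right (-0.87 to -0.66 for WT 1 and KO 3, -1.19 for KO 2) and the other 3 at the lower left.

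Gata6 itself did not read lower in the arrays labelled KO. Its brightest probe set read 11.12, 10.26 and 10.42 log2 in the arrays labelled WT 1 to 3 and 11.58, 11.39 and 11.19 in those labelled KO 1 to 3. The means were 10.60 ± 0.46 and 11.39 ± 0.19 (SD, n = 3 each), a log2 difference of 0.79 (SE 0.24), or 1.73-fold higher in the arrays labelled KO, with an adjusted p of 0.964 in limma. The probe set of intermediate brightness differed by 0.83 (SE 0.31) and the dimmest by 0.36 (SE 0.45), both also higher in the arrays labelled KO. With fluidics station as a block, and equally within station 2, the Gata6 difference was 0.97, with SE 0.36 and adjusted p = 1 for the block and SE 0.21 and adjusted p = 0.791 within station 2. Over the 21 alternatives it ran from 0.62 to 1.10, with an adjusted p from 0.428 to 1. Where these probe sets lie relative to the deleted part of the gene is not known here, so their level checks neither the deletion nor the labels. The level of the targeted gene thus leaves the labels unchecked, and every direction below is a direction between the arrays labelled KO and those labelled WT.

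**Figure D2:**
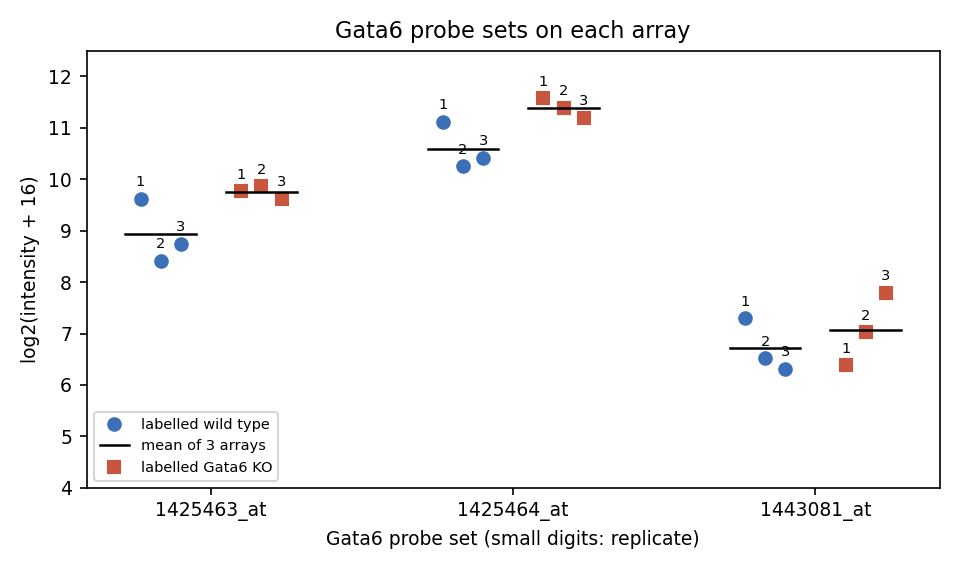
The 3 probe sets that name Gata6, on a log2(intensity + 16) axis; each symbol is 1 array with its replicate number, blue circles labelled WT and red squares labelled KO, and bars are means of 3 arrays. For the brightest probe set, in the middle, all 3 arrays labelled KO (11.19 to 11.58) lie above all 3 labelled WT (10.26 to 11.12).

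Among the relatives and cofactors of Gata6, none of the other 7 members of the list of GATA factors and FOG cofactors passed the test. Gata2, the GATA factor of blood and vascular precursors, differed by -0.42 (SE 0.31) and Gata5 by 0.004 (SE 0.20), and Gata1, Gata3 and Gata4 read near the floor of the arrays in both groups. The FOG cofactors Zfpm1 and Zfpm2, which bind GATA proteins, differed by -0.36 (SE 0.37) and -0.18 (SE 0.27). As a list the 8 members had a median of -0.005 (camera adjusted p = 0.907). Gata6 was the 1 of the 8 with an unadjusted p under 0.05 in limma, and it did not pass over all genes.

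Gene by gene, few differences between the labels stood out from the spread between arrays in limma. A gene that did not pass may still differ, since the simulation recovered 37 of 100 bright genes changed by 1 log2. The bright gene with the smallest p was Dnase1l2, an endonuclease gene, which read 5.06 ± 0.40 log2 in the arrays labelled WT and 9.44 ± 0.62 in those labelled KO (SD, n = 3 each). That is a log2 difference of 4.38 (SE 0.39), and it did not pass over all genes (adjusted p = 0.161). Its size depends on the pseudocount, since the arrays labelled WT read near the floor: it was 5.26 with a pseudocount of 1 and 3.18 with 64, and 3.07 for the mean of all its probe sets. It passed with each array centred on its median (adjusted p = 0.00412) and among the 9096 brighter genes (0.0187), in a range of 0.00412 to 0.986 over 21 alternatives. The other bright genes with the smallest p and higher levels in all 3 arrays labelled KO, none of which passed, were led by Fabp4, a fatty acid binding protein. Fabp4 differed by 1.00 (SE 0.11, adjusted p = 0.343), Rai14 by 0.62 (SE 0.07, adjusted p = 0.343), Emb by 1.21 (SE 0.15, adjusted p = 0.43) and Eci1, an enzyme of fatty acid oxidation, by 1.82 (SE 0.25, adjusted p = 0.5). Those with lower levels in all 3 arrays labelled KO, which did not pass either, included Egfr, the receptor of epidermal growth factor. Snx18 differed by -0.76 (SE 0.11, adjusted p = 0.5), Galnt18 by -1.28 (SE 0.19, adjusted p = 0.5), Bspry by -1.31 (SE 0.21, adjusted p = 0.635) and the collagen gene Col13a1 by -0.46 (SE 0.07, adjusted p = 0.643). The brightest probe set of Egfr differed by -1.74 (SE 0.25, adjusted p = 0.5), and 3 of its 7 probe sets, like 1 of the 2 of Bspry, read higher in the arrays labelled KO. Over their alternatives Egfr ran from -2.08 to -0.481, Bspry from -1.474 to -0.655 and Fabp4 from 0.502 to 1.068.

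In limma, 1 of the 18193 genes passed an adjusted p of 0.05: 5830444B04Rik fell by 0.19 on the log2 scale (SE 0.009, adjusted p = 0.018), from 4.61 ± 0.01 in the arrays labelled WT to 4.42 ± 0.01 in those labelled KO (SD, n = 3 each), near the floor of the arrays. The size of this difference depends on the pseudocount too, at -0.556 with 1 and -0.061 with 64. No gene passed as higher, and 834 genes had an unadjusted p under 0.05, 363 higher and 471 lower, which is 4.58% of those tested. Of 9310 genes bright in at least 1 group, 492 had all 3 arrays labelled KO above all 3 labelled WT and 584 all 3 below, together 11.6% where chance gives 10%. The call on 5830444B04Rik was lost without any single array, with an adjusted p from 0.0651 (without KO 1) to 0.165 (without KO 3). Without WT 1, WT 2, WT 3 and KO 2 it was 0.11, 0.101, 0.0712 and 0.138, and over its 20 alternatives it ran from 0.0105 to 0.628. Without KO 1 the gene that passed was Star, at 0.38 (SE 0.02, adjusted p = 0.0459), and with fluidics station as a block 32 genes passed, all lower and all dim, 10 within station 2.

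Of 40 lists of cell type markers and pathway genes, 17 shifted by camera with a preset correlation between genes, 13 lower and 4 higher in the arrays labelled KO. The other 9 splits of the 6 arrays, which mix the labels, called 4 to 13 lists by the same test. None of the 40 lists passed when the correlation between genes was estimated (2 had an unadjusted p under 0.05), nor by fry (2 at an unadjusted p under 0.05, lowest adjusted p = 0.598). No member of any list passed over all genes tested, and 25 genes passed adjusted over a list alone, Id2 over 2 lists. Of the 224 members of the 17 lists, 162 moved by over 1.5 times when 1 array was left out, 56 of them in sign. Of the 25 genes 1 did, Dhcr7 (-1.03, and -0.681 without KO 3). In a comparison added after the data were seen, the mean of 8 of the 17 lists differed more between WT 1, KO 2 and KO 3 and the other 3 arrays than between the labels: endothelium (-0.594), lymphatic endothelium (-0.582), Wnt targets (-0.242), FGF (-0.321), Hedgehog (-0.33), cell cycle (-0.629), immediate early genes (-0.537) and hypoxia (0.357). Since station 1 holds only arrays labelled WT, the fit with station as a block rests on station 2, the 3 arrays labelled KO against WT 3, and its differences equal those within station 2. The arm labelled WT is then 1 array with no spread of its own, and the errors come from the arrays labelled KO, in the block fit also from WT 1 and WT 2, so these fits say little on whether a call holds. Members named below beyond the first 2 measured of a list were chosen after their values were seen.

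**Figure D3:**
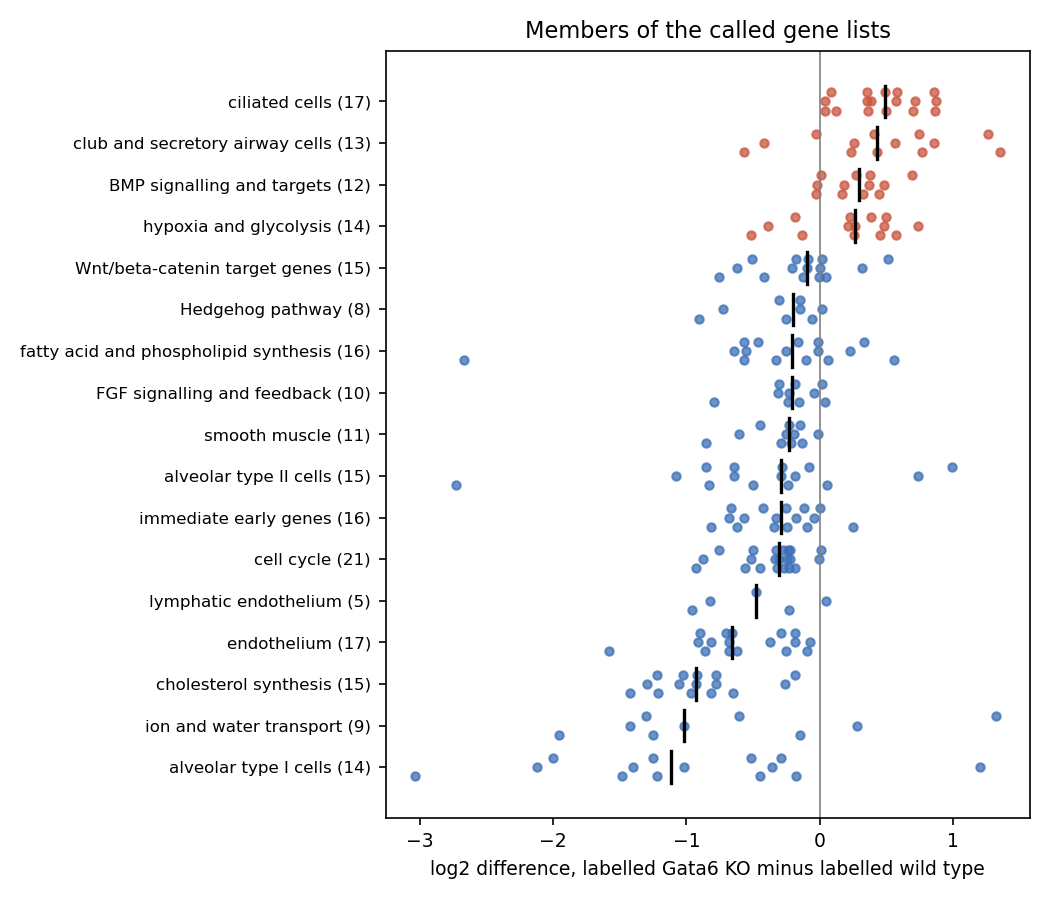
Members of the 17 gene lists that shifted, each point 1 gene and each bar the median of its list; the horizontal axis is the mean log2 difference, arrays labelled KO minus arrays labelled WT (3 each), and the number of measured members stands in parentheses. Lists in blue are lower and those in red higher in the arrays labelled KO, from a median of -1.12 for alveolar type I cells to 0.49 for ciliated cells.

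The cholesterol synthesis list fell in the arrays labelled KO by camera (adjusted p = 2.21e-17), and did not pass with an estimated correlation (adjusted p = 0.664). All 15 measured members read lower, with a median log2 difference of -0.93 and a mean of -0.90. In 11 of them all 3 arrays labelled KO lay below all 3 labelled WT, where chance gives 10% of single genes over both directions. The members vary together (estimated correlation 0.572), so they are not independent and that rate does not measure chance for the list. Hmgcs1, the synthase that opens the mevalonate pathway, read 12.27 ± 0.33 and 11.49 ± 0.45 (SD, n = 3 each; difference -0.78, SE 0.27), and Sqle, which oxidises squalene, differed by -0.92 (SE 0.36). Fdps, which makes farnesyl diphosphate, differed by -1.42 (SE 0.27), and Mvd by -0.93 (SE 0.18). The regulators on the list went the same way: Srebf2, the transcription factor that switches the pathway on, differed by -0.96 (SE 0.21), and Insig1, which restrains it, by -1.06 (SE 0.21). By limma 10 of the 15 members passed adjusted over the list alone and 0 over all genes tested. With station as a block the mean was -0.93 (adjusted p = 3.36e-11, and 1.14e-10 within station 2), in a range of 2.82e-19 to 1.14e-10 over 18 alternatives.

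Genes of fatty acid and phospholipid synthesis, which also supply surfactant lipid, fell as a list as well. Of 16 members 12 read lower (median -0.21, mean -0.32; camera adjusted p = 0.0351, and adjusted p = 0.679 with an estimated correlation). Fasn differed by -0.33 (SE 0.34) and Acaca, the first committed enzyme of fatty acid synthesis, by -0.57 (SE 0.24). The stearoyl-CoA desaturase genes Scd1 and Scd2 differed by -2.67 (SE 0.85) and -0.56 (SE 0.15), while Me1, which supplies NADPH for the pathway, differed by 0.56 (SE 0.21). No member passed adjusted over the list alone or over all genes tested. Quantile normalisation (camera adjusted p = 0.204), median centring, the filter on dim genes and a pseudocount of 64 each ended the call. The call was lost without WT 1 (adjusted p = 0.0963), WT 2 (0.0986), KO 1 (0.0627) or KO 3 (0.0501), and with station as a block the mean was -0.25 (adjusted p = 0.879, and 0.748 within station 2). It held in 8 of 18 alternatives, with an adjusted p from 0.0152 to 0.879.

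Markers of alveolar type I cells, the flat cells of gas exchange, fell as a list in the arrays labelled KO. Of 14 members 13 read lower, with a median of -1.12 and a mean of -1.01 (camera adjusted p = 1.04e-06, and adjusted p = 0.664 with an estimated correlation). Ager, a receptor abundant on these cells, read 15.13 ± 0.24 and 14.68 ± 0.35 (SD, n = 3 each; difference -0.45, SE 0.23), and the water channel gene Aqp5 differed by -1.25 (SE 0.75; -0.536 without KO 1 and -2.05 without KO 2). The tight junction gene Cldn18 differed most, by -3.04 (SE 0.68): it read 13.31, 13.22 and 13.48 in the arrays labelled WT 1 to 3 and 9.18, 11.91 and 9.81 in those labelled KO 1 to 3. By limma 4 of the 14 passed adjusted over the list alone and 0 over all genes tested: Cldn18, Akap5 (-2.12, SE 0.51) and Spock2 (4.01-fold) read lower, and Igfbp2, an insulin-like growth factor binding protein, read higher (1.21, SE 0.25). In 3 of the 14 all 3 arrays labelled KO lay below all 3 labelled WT, and in 1 they lay above. Without KO 1 the mean of the list was -0.61 (camera adjusted p = 0.0237), and without KO 2 it was -1.44 (camera adjusted p = 1.19e-14). With station as a block the mean was -0.66 and the call was lost (adjusted p = 0.103, and 0.0887 within station 2), in a range of 1.19e-14 to 0.103 over 18 alternatives.

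Markers of alveolar type II cells, which make surfactant, fell as a list, but its surfactant protein genes went both ways. Of 15 members 12 read lower (median -0.29, mean -0.44; camera adjusted p = 0.0111, and adjusted p = 0.691 with an estimated correlation), and none passed adjusted over the list alone or over all genes tested. Sftpc read 12.71 in the array labelled KO 1 and 15.74 in KO 2, against a mean of 15.68 ± 0.10 in the arrays labelled WT (SD, n = 3), and Sftpb differed by -0.08 (SE 0.23). Abca3, the lipid transporter of lamellar bodies, differed by -2.73 (SE 1.34), with 6.12 in KO 3 against 11.26 in KO 1. Sftpd differed by 0.99 (SE 0.23) and Sftpa1 by 0.74 (SE 0.55). The call was lost without WT 1 (adjusted p = 0.071), WT 2 (mean -0.28, adjusted p = 0.0996) or KO 1 (mean -0.27, adjusted p = 0.441), and without KO 2 the mean was -0.70 (adjusted p = 0.00012). Quantile normalisation ended the call too (camera adjusted p = 0.0654). With station as a block the mean was -0.13 and the test turned to higher than other genes (adjusted p = 0.926, and 0.979 within station 2). The list was called in 12 of 18 alternatives, with an adjusted p from 0.00012 to 0.979.

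Genes of ion and water transport, which move fluid across the lung epithelium, fell as a list. Of 9 members 7 read lower, with a median of -1.02 and a mean of -0.68 (camera adjusted p = 0.03, and adjusted p = 0.664 with an estimated correlation). The epithelial sodium channel genes Scnn1a, Scnn1b and Scnn1g differed by -0.61 (SE 0.24), -1.42 (SE 0.54) and -1.95 (SE 0.82; -1.152 without KO 1). The water channel gene Aqp4 read 8.60 ± 0.32 and 9.92 ± 0.18 (SD, n = 3 each), higher by 1.32 (SE 0.19), and was the 1 member that passed adjusted over the list alone, with 0 over all genes tested. Quantile normalisation (camera adjusted p = 0.121), the filter on dim genes and preferring probe sets without an s or x suffix each ended the call. The call was lost without WT 1 (adjusted p = 0.168), WT 2 (0.0985) or KO 1 (0.184), and with station as a block the mean was -0.44 (adjusted p = 0.719, and 0.858 within station 2). It held in 10 of 18 alternatives, with an adjusted p from 0.00271 to 0.858.

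The lists of conducting airway markers rose by camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.664 for ciliated and 0.691 for club cells). For ciliated cells all 17 measured members read higher, with a median of 0.49 and a mean of 0.46 (camera adjusted p = 1.94e-05). Foxj1, the master regulator of motile cilia, differed by 0.12 (SE 0.34) and Tekt1 by 0.37 (SE 0.17). Ccdc39 and Ccdc113 differed by 0.87 (SE 0.39) and 0.86 (SE 0.29), and none of the 17 passed adjusted over the list alone or over all genes tested. For club and secretory airway cells 10 of 13 members read higher, with a median of 0.43 and a mean of 0.45 (camera adjusted p = 0.0387). Scgb3a2 differed by 0.24 (SE 0.13) and Cyp2f2 by 1.36 (SE 0.59; 0.734 without WT 1), while Scgb1a1, the main secreted protein of club cells, differed by -0.42 (SE 0.30), and none of the 13 passed adjusted over the list alone or over all genes tested. The ciliated cell call was lost without KO 3 (adjusted p = 0.0713), and its mean was 0.30 without WT 1 (adjusted p = 0.00327). Station as a block gave a mean of 0.01 (adjusted p = 0.879, and 0.979 within station 2), in a range of 1.31e-10 to 0.979 over 18 alternatives. The club cell call was lost without WT 1 (mean 0.18, adjusted p = 0.248) or KO 3 (adjusted p = 0.533), with array quality weights, and with the replicate block (adjusted p = 0.0524). It was also lost with station as a block (mean 0.14, adjusted p = 0.554, and 0.566 within station 2; range 7.24e-05 to 0.566).

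The endothelium list fell in the arrays labelled KO. All 17 members read lower, with a median of -0.66 and a mean of -0.58 (camera adjusted p = 2.37e-09, and adjusted p = 0.664 with an estimated correlation). In 3 of the 17 all 3 arrays labelled KO lay below all 3 labelled WT. In 9 of the 17 WT 1, KO 2 and KO 3 all lay below the other 3 arrays, a split picked after the data were seen. The junction genes Pecam1 and Cdh5 differed by -0.81 (SE 0.40) and -0.91 (SE 0.56). Cldn5, the claudin of endothelial tight junctions, differed by -0.70 (SE 0.14) and was the 1 member that passed adjusted over the list alone, with 0 over all genes tested. Pecam1 was low in the 3 arrays with more signal on unnamed probe sets, at 9.54, 9.19 and 9.18 in WT 1, KO 2 and KO 3, and read 10.72, 10.62 and 10.07 in WT 2, WT 3 and KO 1. With that signal as a covariate, an alternative chosen after the data were seen, the list's adjusted p was 1.04e-11. With station as a block the mean was -0.62 (adjusted p = 2.25e-05, and 6.04e-07 within station 2; range 1.04e-11 to 2.25e-05 over 18 alternatives).

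The lymphatic endothelium and smooth muscle lists fell too, and neither passed with an estimated correlation (adjusted p = 0.691 and 0.664). For lymphatic endothelium 4 of 5 measured members read lower, with a median of -0.48 and a mean of -0.49 (camera adjusted p = 0.0201). Lyve1, a hyaluronan receptor, differed by -0.96 (SE 0.29), Flt4, the receptor of lymphatic growth factors, by -0.82 (SE 0.33), and Prox1, near the floor, by 0.05 (SE 0.08). For smooth muscle all 11 members read lower, with a median of -0.23 and a mean of -0.31 (camera adjusted p = 0.00193). Acta2 differed by -0.23 (SE 0.22) and the smooth muscle myosin gene Myh11 by -0.60 (SE 0.30), and no member of either list passed adjusted over the list alone or over all genes tested. The lymphatic call was lost without WT 2 (mean -0.32, adjusted p = 0.0599), KO 2 (adjusted p = 0.123) or KO 3 (mean -0.32, adjusted p = 0.0713). Station as a block ended it as well (mean -0.34, adjusted p = 0.455, and 0.34 within station 2; range 0.00205 to 0.455). The smooth muscle call was lost without WT 3 (mean -0.17, adjusted p = 0.098) or KO 2 (mean -0.18, adjusted p = 0.0936) and with array quality weights. Its mean was -0.59 with station as a block (adjusted p = 2.43e-05, and 4.48e-05 within station 2; range 3.33e-06 to 0.098).

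Among the signalling pathways of lung growth, the Hedgehog list fell and the BMP list rose by camera, and neither passed with an estimated correlation (adjusted p = 0.664 for both). For the Hedgehog pathway 7 of 8 measured members read lower, with a median of -0.20 and a mean of -0.32. In 5 of them all 3 arrays labelled KO lay below all 3 labelled WT, where chance gives 10% of single genes over both directions. The members are not independent (estimated correlation 0.155), so that rate does not measure chance for the list. The camera adjusted p was 0.000477. The ligand gene Shh differed by -0.15 (SE 0.10) and its receptor gene Ptch1, itself switched on by the pathway, by -0.30 (SE 0.11). Gli1, a transcription factor and target of the pathway, differed by -0.90 (SE 0.23) and Foxf1 by -0.73 (SE 0.22), and no member passed adjusted over the list alone or over all genes tested. For BMP signalling and targets 10 of 12 members read higher, with a median of 0.30 and a mean of 0.27 (camera adjusted p = 0.00172). Bmp4 differed by 0.32 (SE 0.32) and Bmp2 by 0.37 (SE 0.18), and Id2, an inhibitor of differentiation that BMP switches on, by 0.48 (SE 0.10), the 1 member that passed adjusted over the list alone, with 0 over all genes tested. With station as a block the Hedgehog mean was -0.38 (adjusted p = 0.00375, and 0.00114 within station 2; range 9.8e-05 to 0.0346 over 18 alternatives). The BMP mean was then 0.18 and its call was lost (adjusted p = 0.103, and 0.0887 within station 2; range 3.41e-05 to 0.103).

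The lists of Wnt targets and of the FGF pathway fell as well by camera, and neither passed with an estimated correlation (adjusted p = 0.664 for both). Of 15 measured Wnt/beta-catenin target genes 10 read lower, with a median of -0.10 and a mean of -0.14 (camera adjusted p = 0.03). Axin2, a feedback inhibitor of the pathway, differed by -0.51 (SE 0.24), Apcdd1, also an inhibitor, by -0.75 (SE 0.28), and Lef1 read near the floor. Of 10 genes of FGF signalling and feedback 8 read lower, with a median of -0.21 and a mean of -0.22 (camera adjusted p = 0.0338). The receptor gene Fgfr2 differed by -0.31 (SE 0.12) and the ligand gene Fgf7 by -0.04 (SE 0.13), and no member of either list passed adjusted over the list alone or over all genes tested. The Wnt target call was lost without WT 2 (adjusted p = 0.0941), KO 2 (0.0936) or KO 3 (mean -0.03, adjusted p = 0.0803), and its mean was -0.24 without KO 1 (adjusted p = 0.0337). It was lost too with station as a block (mean -0.20, adjusted p = 0.171, and 0.0887 within station 2) and with the covariate for unnamed probe sets (adjusted p = 0.111). Array quality weights, median centring, quantile normalisation (adjusted p = 0.116) and the filter on dim genes ended it too, and it held in 8 of 18 alternatives (range 0.0177 to 0.171). The FGF call was lost without WT 3 (adjusted p = 0.0533), KO 2 (0.125) or KO 3 (mean -0.13, adjusted p = 0.0713) and with the replicate block (adjusted p = 0.0592). Station as a block ended it too (mean -0.29, adjusted p = 0.12, and 0.0887 within station 2). So did quantile normalisation (adjusted p = 0.116) and preferring probe sets whose names lack an s or x suffix, and it held in 10 of 18 alternatives (range 0.0322 to 0.125).

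The cell cycle and immediate early gene lists fell by camera, and the list of hypoxia and glycolysis rose. None of the 3 passed with an estimated correlation (adjusted p = 0.691, 0.664 and 0.733). For the cell cycle 20 of 21 measured members read lower, with a median of -0.30 and a mean of -0.37 (camera adjusted p = 3.33e-05). Mki67 and Top2a, markers of dividing cells, differed by -0.23 (SE 0.27) and -0.23 (SE 0.35), and Mcm5, part of the helicase that opens DNA for replication, by -0.93 (SE 0.35). For immediate early genes 14 of 16 members read lower, with a median of -0.29 and a mean of -0.32 (camera adjusted p = 0.000382). Fos differed by -0.43 (SE 0.15), Zfp36 by -0.66 (SE 0.29), and Fosb read at the floor. For hypoxia and glycolysis 10 of 14 measured members read higher, with a median of 0.26 and a mean of 0.20 (camera adjusted p = 0.0298). The glucose transporter gene Slc2a1 differed by 0.22 (SE 0.15) and the glycolytic enzyme gene Pgk1 by 0.45 (SE 0.16), while Vegfa, the vascular growth factor, differed by -0.51 (SE 0.43). No member of these 3 lists passed adjusted over the list alone or over all genes tested.

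Single arrays and the fluidics station weighed on these 3 lists in different ways. The cell cycle call was lost without KO 2 (mean -0.20, adjusted p = 0.117), and its mean was -0.14 without WT 3 (adjusted p = 0.0488), and -0.58 without KO 1 (adjusted p = 5.02e-06). Fitting station as a block gave -0.82 (adjusted p = 1.71e-12, and 5.61e-11 within station 2; range 1.71e-12 to 0.117 over 18 alternatives). Members of this list read low in the arrays with more signal on unnamed probe sets: Mcm5 was at 9.79, 9.07 and 9.06 in WT 1, KO 2 and KO 3 and at 10.29, 10.80 and 9.97 in WT 2, WT 3 and KO 1. In 12 of the 21 cell cycle members WT 1, KO 2 and KO 3 all lay below the other 3 arrays. In 1 of the 21 all 3 arrays labelled KO lay below all 3 labelled WT. The immediate early genes had a mean of -0.51 without KO 1 (adjusted p = 6.15e-05), -0.15 without KO 3 (adjusted p = 0.00692) and -0.51 with station as a block (adjusted p = 0.000256, and 0.000208 within station 2; range 6.15e-05 to 0.0155). Egr1 followed the same arrays, at 6.97, 7.12 and 7.27 in WT 1, KO 2 and KO 3 and 8.14, 8.87 and 8.84 in the other 3. In 8 of the 16 immediate early genes WT 1, KO 2 and KO 3 all lay below the other 3 arrays. In 2 of the 16 all 3 arrays labelled KO lay below all 3 labelled WT. The hypoxia call was lost without WT 2 (adjusted p = 0.0985), WT 3 (mean 0.13, adjusted p = 0.35) or KO 3 (mean 0.13, adjusted p = 0.735), and its mean was 0.34 without WT 1 (adjusted p = 1.74e-05). With station as a block that mean was 0.36 (adjusted p = 6.79e-05, and 6.96e-06 within station 2), and with the covariate for unnamed probe sets the call was lost (adjusted p = 0.158; range 6.96e-06 to 0.735). Members of the hypoxia list read high in those arrays: Bnip3 was at 12.58, 12.32 and 12.79 in WT 1, KO 2 and KO 3 and at 11.36, 11.53 and 11.79 in WT 2, WT 3 and KO 1.

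The other 23 lists did not pass, with a camera adjusted p from 0.0834 to 0.949, and 12 of them passed in at least 1 of the alternatives. General epithelial genes, among them Epcam (0.41, SE 0.40) and Cdh1 (-0.004, SE 0.27), had a median of 0.08 (adjusted p = 0.444). Lung bud progenitor genes, with Sox9 at 0.38 (SE 0.36), had a median of 0.11 (adjusted p = 0.382), and Id2, also on the BMP list, passed adjusted over this list alone. Basal and stratified epithelium (median 0.009, adjusted p = 0.3), whose Krt5 and Krt14 read near the floor, and neuroendocrine cells (0.003, adjusted p = 0.907), whose Chga and Chgb did too, were mostly dim. In the mesenchyme, fibroblast and matrix genes had a median of -0.06 (adjusted p = 0.136), with Col1a1 at -0.17 (SE 0.27) and Col1a2 at 0.01 (SE 0.15). Pericyte genes had one of -0.07 (adjusted p = 0.532), with Pdgfrb at 0.07 (SE 0.30) and Cspg4 at -0.13 (SE 0.34), and mesothelial genes one of -0.22 (adjusted p = 0.482), with Msln at -0.18 (SE 0.31) and Upk3b at -0.39 (SE 0.52). Macrophage and monocyte genes had a median of -0.13 (adjusted p = 0.143), with Cd68 at -0.41 (SE 0.25) and Csf1r at 0.25 (SE 0.20). That list passed in 6 of 18 alternatives, 4 of them without single arrays, with an adjusted p from 0.000284 to 0.979 and a mean from -0.365 to 0.09. Neutrophil genes had a median of -0.01 (adjusted p = 0.907), with S100a8 at -0.26 (SE 0.39) and S100a9 at -0.16 (SE 0.29). Lymphocyte and thymus genes had a median of 0.004 (adjusted p = 0.195), with Cd3e and Cd3g at the floor, and erythroid genes one of -0.009 (adjusted p = 0.532), with Hba-a1 at the floor and Hbb-bh1 at -0.19 (SE 0.24). Of the 12 erythroid genes 8 were measured, Hbb-b1 not among them, and 6 of the 8 were dim, so that list says little on erythroid cells. Whether the floor reading of Hba-a1 comes from the RNA or from its probe set was not tested.

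Neighbouring tissues left little trace by label. Cardiac muscle genes had a median of 0.04 (adjusted p = 0.907), with Myh6 at 0.24 (SE 0.50) and Myh7 at 0.27 (SE 0.65). Skeletal muscle genes had a median of 0.003 (adjusted p = 0.907), with Acta1 and Myh3 near the floor, and cartilage genes one of 0.002 (adjusted p = 0.907), with Col2a1 at the floor and Col9a1 at 0.77 (SE 0.96). Liver genes had a median of -0.02 (adjusted p = 0.598), with Alb at 1.57 (SE 1.2) and Afp at -0.61 (SE 0.89), and nerve and glia genes 0 (adjusted p = 0.41), with Sox10 near the floor and Fabp7 at 0.10 (SE 0.18). Among pathways, Wnt ligands and receptors had a median of -0.05 (adjusted p = 0.104), with Wnt2 at -0.31 (SE 0.18), and the receptor gene Fzd2 at -0.64 (SE 0.26). Notch pathway genes had a median of -0.06 (adjusted p = 0.0834), with Notch1 at -0.43 (SE 0.27) and Notch2 at 0.05 (SE 0.15). Heat shock genes had a median of 0.01 (adjusted p = 0.907), with Hspa1a at 0.08 (SE 0.19) and Hspa1b at 0.02 (SE 0.53). Interferon response genes had a median of -0.04 (adjusted p = 0.173), with Ifit1 at 0.04 (SE 0.20) and Ifit2 at -0.77 (SE 0.25). Glucocorticoid response genes had a median of -0.17 (adjusted p = 0.949), with Tsc22d3 at -0.21 (SE 0.26) and Fkbp5 at -0.37 (SE 0.37), and xenobiotic metabolism genes one of 0.06 (adjusted p = 0.199), with Cyp4b1 at 0.30 (SE 0.22). The median, the mean and the test differed in sign for pericytes (median -0.07, mean 0.05, test lower), neuroendocrine cells (0.003, -0.07, lower), neutrophils (-0.01, 0.07, higher), cartilage (0.002, 0.04, lower), liver (-0.02, 0.05, lower) and the glucocorticoid response (-0.17, 0.14, higher).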

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

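The RNA composition covariate and the fit on fluidics station 2 were chosen after the data were seen. Over the alternatives the number of genes past the threshold was 0 without the intensity trend (910 at an unadjusted p under 0.05), with all probe sets tested (1394), with the replicate block (605), with the RNA composition covariate (1335) and with a minimum of 1.5-fold. It was 32 with the fluidics station block and 10 with fluidics station 2 arrays only, all lower and all dim, 1 and 0 of them shared with the gene reported. Cym, for example, was at 8.01 in the array labelled WT 3 and between 4.49 and 4.53 in the others, so that a single array sets its call. The shared gene, 5830444B04Rik, read alike in the arrays labelled WT 1, WT 2 and WT 3, at 4.613, 4.596 and 4.617. Leaving out single arrays gave 0 to 1 genes, with fewer arrays in the fit. The number of lists called was 7 with the fluidics station block and 7 within station 2, and 0 with an estimated correlation and 0 by fry (2 at an unadjusted p under 0.05 each). It ran from 12 to 17 without single arrays. Quantile normalisation gave 12 lists, 8 lower and 4 higher, and median centring 18, 11 lower and 7 higher. In the alveolar type II list the mean stayed negative (-0.13 in both station fits) while the test turned to higher. The cause was not tested beyond the change in construction that each alternative names. In all 18 settings other than the estimated correlation and fry, 4 lists kept their call and direction: cholesterol synthesis, endothelium, Hedgehog pathway and immediate early genes. All 18 settings use the preset correlation of 0.01, against estimates of 0.572, 0.366, 0.155 and 0.412 for these lists. The 18 settings thus share the same assumption, and none of the 4 lists passed with the estimate. Endothelium, Hedgehog and immediate early genes also differed more between WT 1, KO 2 and KO 3 and the other arrays than between the labels. The 2 station fits among the 18 settings rest on WT 3 as the only array labelled WT compared. Of 1988 values of 96 named genes under alternatives, 1817 kept direction and side, 12 no longer passed, 2 newly passed, and 157 that never passed changed sign. Of 788 list values, 587 kept both, 100 lost and 25 gained a call, 74 uncalled ones changed sign and 2 called ones reversed. Median centring and quantile normalisation moved the median difference of all genes from 0.003 to -0.03 and -0.0006. Genes near the floor, around 4.4 log2, carry little signal over background, and differences there are limited by it.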

Other observations

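The tests of exchanged labels of 1 array per group, of probe sets outside the deleted part and of splits of the arrays by called lists were chosen after the result was seen. Several genes outside the lists that shifted differed between the labels, named here after their values were seen. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, read higher by 1.55 (SE 0.29) and 1.42 (SE 0.37), with Mt1 at 11.61 ± 0.44 and 13.16 ± 0.40 (SD, n = 3 each). Lcn2, an iron-sequestering protein of inflamed epithelium, differed by 1.54 (SE 0.33), and Gsto1, a glutathione transferase, by 2.30-fold. The small matrix proteoglycan genes Lum and Dcn differed by 1.47 (SE 0.31) and 1.10 (SE 0.20), while Col13a1 differed by -0.46 (SE 0.07), and the epithelial mucin gene Muc1 differed by -1.07 (SE 0.19). Each passed adjusted over its own list alone, and none passed over all genes tested in limma.

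Of the genes that neighbour Gata6 on its chromosome, Lama3, a laminin chain of epithelial basement membrane, read 10.76 ± 0.48 and 9.32 ± 0.31 (SD, n = 3 each), a difference of -1.44 (SE 0.28), while 1 of its 2 probe sets read higher in the arrays labelled KO. It passed adjusted over the list of neighbours alone and not over all genes tested (limma adjusted p = 0.829). Npc1, which exports cholesterol from lysosomes, differed by -0.74 (SE 0.19) and Rock1 by 0.31 (SE 0.12). The sex-linked genes differed within the labels: the Y-linked Eif2s3y read 10.27, 10.28 and 10.65 in WT 2, KO 1 and KO 2 and 4.65, 5.05 and 5.70 in WT 1, WT 3 and KO 3. Xist read 12.97, 12.32 and 13.39 in WT 1, WT 3 and KO 3, 7.65 and 6.82 in WT 2 and KO 1, and 9.46 in KO 2. The array labelled KO 2 thus read well above the floor in both Xist and Eif2s3y, and whether it holds the RNA of 1 embryo is not known here. Kdm5d and Uty followed Eif2s3y, at 8.29, 8.89 and 8.96 and at 7.67, 8.04 and 8.02 in WT 2, KO 1 and KO 2.

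The first pattern is the split of the arrays labelled WT 1, KO 2 and KO 3 from the other 3 on the first principal component. RNA degradation was predicted to part the sides in the 3' to 5' ratios of both controls. The ratio of Gapdh did not part them, with a gap of -0.0857 log2, an overlap larger than its SD of 0.0466. Gapdh hardly varied, though, from -0.375 (WT 3) to -0.284 (KO 1), so it could show little of a degradation. Actb leaned toward degradation, at 1.159, 1.069 and 1.301 against 0.899, 0.890 and 1.076 (gap -0.007, SD 0.111). These ratios thus do not decide on degradation. A larger share of nuclear and unspliced RNA is a candidate explanation, since bright unnamed probe sets differed between the sides by 0.82 log2 more than named ones (0.68 for 2361 unnamed and -0.14 for 19616 named). An exchange of the labels WT 1 and KO 1 cannot be told apart from the labels as given: Gata6 would then differ by 0.48 (SE 0.35), above 0 by more than its error, but this bound, set beforehand, holds only if the probe sets read the deleted part, which is not known here.

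The 6 arrays make 10 splits, too few for a share under 0.05: 2 of the 10 called at least as many genes as the labels (1, highest other 3) and 1 of the 10 as many lists (17, highest other 13). The split of WT 1, KO 2 and KO 3 from the rest, picked from the first principal component, had 3536 genes at an unadjusted p under 0.05, against 834 for the labels, and limma called 0 genes in it after adjustment.

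The second pattern is the higher level of Gata6 in the arrays labelled KO. An exchange of 1 array per group cannot be told apart from the labels as given: over the 9 exchanges the Gata6 difference ran from -0.091 (SE 0.404) to 0.738 (SE 0.273), and such values bear on the labels only if the probe sets read the deleted part. That the probe sets lie outside the deleted part may account for the level. It cannot be told apart from an intact gene: 2 of the 3 probe sets read higher by more than their standard error, and the place of none of them is known here. The genotype itself, or a compensating rise of a transcript that the deletion leaves, was not tested.

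The third pattern is the array labelled KO 1, which read high in Tff3, Guca2a and Spink4, genes of intestinal and airway mucous cells, at 10.13, 9.62 and 9.83. The array labelled WT 3 came next, at 8.31, 7.79 and 7.50. Intestine or stomach carried over in dissection are argued against for KO 1 only, as far as the listed genes are active there at this age, which was not tested. The medians of 13 measured enterocyte and 10 stomach genes in KO 1 stood 0.00397 and 0.00386 log2 above those of the other arrays. The abundant Fabp1, Fabp2 and Apoa4 read at the floor (4.71, 4.40 and 4.46). In all 13 enterocyte and 9 of the 10 stomach genes the mean over all arrays lay at or below the median of the genes' means. Carry-over in WT 3 was not tested. An airway goblet cell programme may account for the high levels in KO 1 and stays open. The median of 12 goblet cell genes, listed after the pattern was seen, stood 0.45 log2 above the other arrays, between the bounds set for it. Spdef stood at 2.29, Fcgbp at 2.04, Muc16 at -0.957 and Muc5ac at -0.02. In 9 of the 12 the mean over all arrays lay at or below the median of the genes' means. Of the goblet genes, Muc5b is also on the club cell list and Tff1 on the stomach list, and the genotype as the source was not tested.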
